A study of Mus musculus with 12 samples.

How the data were processed

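The data are RNA-seq libraries of endothelial cells sorted from the ventricles of mouse embryos, 12 in all. Groups were taken from the sample labels and the batch from the batch label, which runs from 1 to 4 at E13 and takes 2 further values at E17. Each batch holds 1 endocardial and 1 coronary library of 1 stage. Per the labels' protocols, RNA was isolated from freshly sorted cells with a PicoPure kit, polyadenylated RNA was selected, and NEBNext Ultra libraries, which do not mark strand, were sequenced as single reads on an Illumina instrument.

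The deposited values are expected counts per gene, which need not be whole, and 18.3% of them are not. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.3 and RSEM 1.2.3 were used with build GRCm38, and the roles and settings of the tools are not given in the sources used here. RSEM divides reads that fit several genes between them by an estimate, so counts of near-identical copies, such as processed ribosomal pseudogenes, are uncertain, and without strand a gene and its antisense partner cannot be separated. The table holds 41214 genes by Ensembl identifier in 12 columns, each matched to 1 sample by its title. Symbols were found for 40254 identifiers and GRCm38 coordinates, from a GENCODE annotation of that build, for 40340.

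Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with its default minimum count of 10 and total of 15, which left 15171. The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with TMM normalization and 1 fit of 4 group means over all 12 libraries, so that groups of 2 libraries share the spread of all groups, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.126. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 5 comparisons were coronary minus endocardial at E13 and at E17, E17 minus E13 in endocardial and in coronary libraries, and the difference of the population effect between stages. CPM values use TMM-scaled library sizes. The CPM ratios given with an exact interval instead divide the pooled counts of each group by its unscaled library totals. They can therefore differ from the ratio of the mean CPM values.

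Gene lists were fixed before the data were examined, and 465 of their 469 entries are in the table. They cover endothelial identity (endocardial, heart capillary, arterial, venous, tip cell, pan-endothelial, lymphatic), pathways (Notch, BMP and TGF-beta, Wnt targets, VEGF and angiopoietin, guidance, flow response, interferon), growth and metabolism (cell cycle, glycolysis, fatty acid, imprinted, fetal timing), matrix and contacts (basement membrane, valve and transition, junctions), stress (immediate early) and other cells (cardiomyocyte, epicardial, fibroblast, mural, erythroid, leukocyte, platelet, neural crest and glial). Some genes stand on several lists. Each list with at least 5 tested members was tested with camera in limma 3.58.1, on both sides, with a preset correlation of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation. Of the 155 list tests, the signs of the median, the mean and the test differed in 24, of which 0 were called. Overlaps of the E13 and E17 calls were set against n1 × n2 / N.

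Genes named in the text follow a rule fixed before the data were examined. It takes, per comparison, the 6 largest rises and 6 largest falls among genes that passed, differed at least 2-fold, had at least 10 CPM in the higher group, did not overlap between the groups (not asked of the difference between stages) and were not predicted models. It adds for each list up to 4 members with the smallest adjusted p and the most abundant member that did not pass, all members of a count of 5 or fewer, and the genes of the gate. Members beyond these are named only in plain lists or where their value completes a statement. Some genes that the rule takes are not reported here.

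Replicate libraries of a group differed by more than counting noise, with a chi-square per gene from 4.39 to 39.4, so none was counted as a repeat of another. The shared batch label pairs an endocardial with a coronary library. Over 9722 genes, deviations from the group means correlated at 0.088, 0.546, 0.189 and 0.36 within the E13 batches 1 to 4, and from -0.422 to 0.239 between E13 batches. At E17, where 2 libraries per group allow only 1 value up to its sign, it was 0.194 within and -0.194 between batches. These are correlations across genes, which are not independent replicates. The batch was kept as a block in an alternative fit, which cannot be made for the stage comparisons because each batch holds 1 stage.

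The test was checked on counts simulated from 1 mean per gene over all 12 libraries and the real library sizes and dispersions. Few genes were changed, so a setting with most genes called, as in the real E13 comparison, was not checked. In the simulated E13 comparison on 14784 genes, 89.4% of 66 genes changed 4-fold and 53.7% of 67 changed 2-fold were recovered, with 5 false calls among 137. In the simulated E17 comparison on 14754 genes, 80.3% of 66 and 59.7% of 67 were recovered, with 4 false calls among 120. For the simulated difference between stages, 75.8% of 66 changed 4-fold, 58.2% of 67 changed 2-fold and 29.85% of 67 changed 1.5-fold were recovered. There, 8 of 117 calls were false. In camera on simulated E13 data, a list of 20 genes shifted 1.5-fold was called and 0 of 99 random lists were. Genes were drawn independently there, so false calls of lists whose members move together were not checked. In the real E13 comparison the estimated correlation reached 0.83 in the fibroblast list. Library totals ran from 14973633 to 27360653, and intervals and floors on low counts cover counting error only. A gene at 0 in a whole group was set against a floor of 3 counts over the group.

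Alternatives were DESeq2 1.42.0 size factors in place of TMM, the DESeq2 Wald test, limma-voom, and voom with batch as a random effect (estimated correlation 0.133). Others were no low-count filter, a filter of 5 CPM in 2 libraries, only the groups compared, the batch block and each library left out in turn. Further ones thinned all libraries to the smallest, or removed 91 genes before scaling. Those genes were mitochondrial genes and the cardiomyocyte, erythroid, leukocyte and platelet lists. The fibroblast, mural, epicardial, valve and glial lists were kept, so their share in the calls was not tested this way. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. No reads were realigned, and no value was left out beyond the filters named.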

Results

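The series holds bulk RNA-seq of sorted endothelial cells from embryonic mouse hearts, with 2 populations at 2 stages and 12 libraries in all. The endocardial population lines the heart chambers, and the coronary population comes from the vessels that grow within and over the ventricular wall. The embryos carried Nes-gfp, a transgene in which nestin regulatory sequence drives green fluorescent protein (GFP). Atria and the aortic region were removed, the ventricles were digested with an enzyme. The cell fractions were collected by flow cytometry in 1 session per suspension. Each population has 4 libraries at the earlier embryonic stage (E13) and 2 at the later one (E17). The E17 embryos also carried an inducible nestin Cre and a tomato reporter, and 0.1 ug of tamoxifen was given 2 days before collection.

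Cells had to be alive, negative for the red cell marker Ter119 and the leukocyte marker CD45, and positive for CD31, the product of Pecam1. At E13 the endocardial gate then took cells low in GFP and high in endomucin (Emcn), and the coronary gate took GFP-positive cells. At E17 the endocardial gate is described only as GFP-positive. The study describes 2 coronary gates at E17, an arterial and capillary one and a venous one, both low in endomucin. The labels do not say which of them gave the E17 coronary libraries. Totals of expected counts ran from 17395783 to 27360653 in the E13 endocardial libraries, from 17677860 to 21560343 in the E13 coronary libraries, and from 14973633 to 19168912 at E17. Between 17818 and 19240 genes had a count in a library. The labels do not say whether replicate libraries came from separate litters, so p-values measure the spread between these libraries only. Values in CPM, counts scaled to a common library size, are given as mean ± SD, with n = 4 libraries per group at E13 and n = 2 at E17, and log2 fold changes as estimate ± SE. The SE is the absolute log2 fold change over the square root of edgeR's quasi-likelihood F statistic. For genes with a few counts in a group it can understate the error, and the exact intervals given for such genes are wider.

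The first principal component of log2 CPM held 48.52% of the variance and set all 6 coronary libraries apart from all 6 endocardial libraries. The second held 24.08% and parted the stages, more widely in the coronary libraries (from 28.2 to 58.3 at E13, -84.0 and -70.9 at E17) than in the endocardial ones (from 5.04 to 9.15 at E13, -32.3 and -27.5 at E17).

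**Figure D1:**
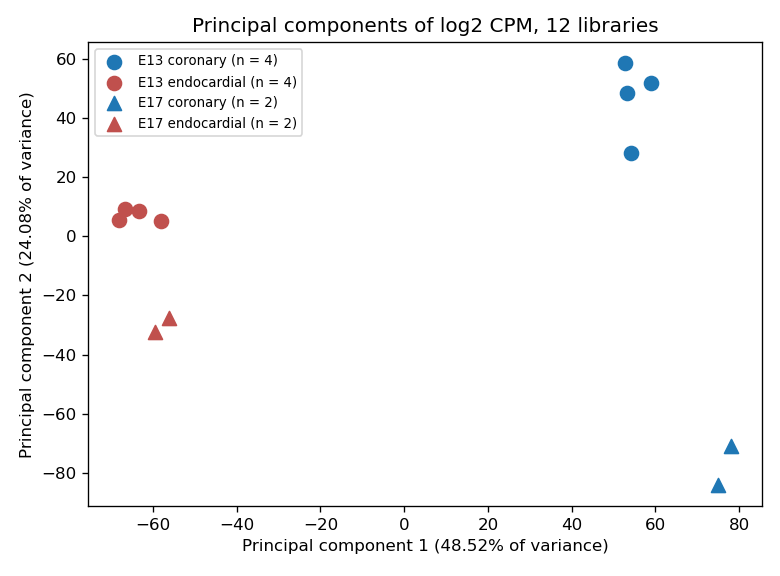
Principal components 1 and 2 of log2 CPM over 15171 genes, in arbitrary units, with 1 point per library, coloured by population and shaped by stage. Component 1 carries 48.52% of the variance and component 2 carries 24.08%, and the 4 groups occupy separate places.

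Emcn, which encodes the surface sialomucin endomucin, stood at 534 ± 11.8 CPM in E13 endocardial and 163 ± 23.1 CPM in E13 coronary libraries, and at 992 ± 165 and 221 ± 13.6 CPM in the E17 endocardial and coronary libraries. Its coronary minus endocardial log2 fold change was -1.71 ± 0.10 at E13 (edgeR adjusted p = 3.71e-08) and -2.17 ± 0.14 at E17 (edgeR adjusted p = 1.24e-07). Nes, the gene of the reporter, was higher in coronary libraries by 0.92 ± 0.08 at E13 and 2.07 ± 0.11 at E17, with means of 262 ± 17.7, 497 ± 52.7, 151 ± 6.74 and 633 ± 42.8 CPM in the order E13 endocardial, E13 coronary, E17 endocardial, E17 coronary. Its mean was thus lowest in the E17 endocardial libraries, whose gate is described as GFP-positive. Pecam1 differed less between populations than Emcn and Nes did, and in opposite directions, -0.26 ± 0.10 at E13 and 0.39 ± 0.13 at E17. It lay between 1024 ± 158 CPM in E13 coronary and 1971 ± 241 CPM in E17 coronary libraries. Neither Pecam1 call was firm: the edgeR adjusted p was 0.0609, 0.0524 and 0.0897 without E13 endocardial replicates 1, 3 and 4 and 0.101, 0.112 and 0.0781 without E13 coronary replicates 2, 3 and 4 in the E13 comparison, and 0.104 and 0.082 without E17 endocardial replicates 1 and 2 and 0.204 without E17 coronary replicate 2 in the E17 comparison. The change of the Pecam1 difference between stages, 0.65 towards coronary cells at E17, passed the edgeR test. Pecam1 also passed as higher in E17 than in E13 coronary libraries. Ptprc, which encodes CD45, was too low to be tested.

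The E13 comparison asks how coronary and endocardial endothelium differ while the coronary plexus is forming. Genes of heart capillaries, arteries, sprouting tip cells, glycolysis and the cell cycle were higher in coronary libraries, and interferon-pathway genes and part of the endocardial set were lower. Of the 15 heart capillary genes, 14 were higher, among them the transcription factor gene Meox2 (5.88 ± 0.30, from 0.499 ± 0.204 to 31 ± 9.25 CPM) and the water channel gene Aqp1 (3.33 ± 0.16). Timp4 was the exception at 0.04 ± 0.49, with 0.212 ± 0.179 CPM in E13 coronary libraries. Of the 18 arterial genes, 14 were higher, led by the netrin receptor gene Unc5b (4.43 ± 0.09) and the Notch effector gene Hey2 (4.36 ± 0.15), while Gja4, Nrp1 and Bmx were lower and Efnb2 lay at 0.15 ± 0.09. The largest coronary excess among genes that passed the naming rule was in Wnt7a, a Wnt ligand gene (8.47 ± 0.51, 0.0188 ± 0.0376 against 10.7 ± 2.82 CPM), with 2 counts in E13 endocardial and 858 in E13 coronary libraries, a CPM ratio of 487 (95% exact interval 134 to 4030.0).

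Most tip cell, glycolysis and cell cycle genes were higher in E13 coronary libraries. Of the 14 tip cell genes, 12 were higher in coronary libraries, including the secreted peptide gene Apln (5.32 ± 0.27) and the placental growth factor gene Pgf (3.87 ± 0.17). Trp53i11 was lower, and Lamb1 lay at 0.03 ± 0.07. All 16 glycolysis genes were higher, with Pfkp, a phosphofructokinase gene, at 2.81 ± 0.13 and Gapdh at 1.21 ± 0.09. Of 32 cell cycle genes, 30 were higher, such as Birc5 (1.22 ± 0.11) and Cenpa (1.10 ± 0.08), and Mcm2 and Mcm4 lay at 0.02 ± 0.05 and 0.10 ± 0.06. 10 of the 13 Wnt target genes were higher, among them Lef1 (4.16 ± 0.36), Apcdd1 (2.39 ± 0.14) and Nkd1 (2.11 ± 0.12), whereas Sox7 was lower, Ccnd1 lay at -0.24 ± 0.10 and Sp5 at -0.02 ± 0.59. With the batch as a block, Ccnd1 passed the test as lower (edgeR adjusted p = 0.00505). Of the 8 Wnt target genes with at least 10 CPM in E13 coronary libraries, 6 were lowest in replicate 1 and 5 were highest in replicate 3. Lef1 was among both, with a log2 ratio of 1.85 of replicate 3 over replicate 1.

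Endocardial genes were split at E13. Of the 15 on that list, 8 were lower in coronary libraries, with the natriuretic peptide receptor gene Npr3 at -2.91 ± 0.15 (1680.0 ± 62.9 against 224 ± 57.1 CPM) and Cdh11, a cadherin gene, at -2.03 ± 0.10. Tbx20, Hapln1, Bmp6 and Edn1 were higher, and Nfatc1, Gata4 and Gata5 did not pass at 0.10 ± 0.06, 0.15 ± 0.09 and -0.17 ± 0.12. Among 12 venous genes the transcription factor gene Nr2f2 (-1.70 ± 0.05), Vwf (-1.71 ± 0.10), Dab2 and Ephb4 were lower, and Aplnr (3.00 ± 0.18), Nrp2, Flt4, Selp and Vcam1 were higher. The MHC class I and interferon list had 16 of 20 members lower, among them Bst2 (-1.49 ± 0.07). H2-D1 was higher, and H2-K1 (0.83 ± 0.36), H2-T23 (0.05 ± 0.16) and Irf1 (-0.18 ± 0.14) did not pass, although H2-K1 rose and Irf1 fell once batch was a block (edgeR adjusted p = 0.00178 and 0.039). 7 of 15 imprinted growth genes were lower, with Plagl1 at -1.88 ± 0.06, Cdkn1c at -2.56 ± 0.15 and H19 at -0.94 ± 0.06, and Meg3, Grb10, Peg10, Zim1 and Dcn were higher. Among the largest falls were Apob, the gene of the main low-density lipoprotein protein (-5.67 ± 0.46), the plasma inhibitor chain gene Itih3 (-3.83 ± 0.21) and the desmosomal cadherin gene Dsg2 (-3.76 ± 0.17).

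Markers of other cell types were also higher in the E13 coronary libraries. All 11 fibroblast genes were higher, with the collagen gene Col1a1 at 5.28 ± 0.47 (18.2 ± 7.05 against 710.5 ± 330.1 CPM), Dcn at 3.67 ± 0.30 and Mfap4 at 5.46 ± 0.49. Of the 15 valve and endothelial-to-mesenchymal transition genes, 11 were higher, such as the hyaluronan synthase gene Has2 (6.12 ± 0.36) and the proteoglycan gene Vcan (2.98 ± 0.20), Tgfbr3 and Zeb2 were lower, and Postn and Tgfb2 lay at 0.63 ± 0.27 and 0.28 ± 0.18. Among 12 mural cell genes, 7 were higher, with Tagln at 4.73 ± 0.45 and the potassium channel gene Kcnj8 at 4.65 ± 0.19, while the pericyte receptor gene Pdgfrb lay at -0.47 ± 0.27 and passed only with the batch block (edgeR adjusted p = 0.0487). 8 of 10 epicardial genes were higher, among them Wt1 (2.98 ± 0.25) and Tbx18 (4.47 ± 0.54), Lrrn4 was lower and Upk3b lay at 1.13 ± 0.51. The fibroblast genes differed between coronary replicates, with Col1a1 at 284.7 CPM in replicate 1 and 1084 CPM in replicate 3, while Pecam1 stood at 1237 and 861.0 CPM in those libraries. Tagln followed the fibroblast genes, whereas the mural genes Kcnj8 and Abcc9 were highest in replicate 1 and lowest in replicate 3. The 2 epicardial genes with at least 10 CPM in E13 coronary libraries parted. In replicate 3, 1 was highest and 1 lowest (log2 ratios of 2.351 and -0.949 over replicate 1). Of the genes with at least 10 CPM in E13 coronary libraries, all 11 capillary genes (median log2 ratio -1.02 of replicate 3 over replicate 1), 14 of 15 glycolysis genes and 11 of 13 tip cell genes were also lowest in replicate 3. None of the 17 cardiomyocyte genes was higher, and Myh7, a heavy chain gene of cardiac myosin, had 87.8 ± 20.8 and 73.2 ± 33.6 CPM.

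In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9106 of 15171 genes passed 0.05 at E13, 4568 higher and 4538 lower in coronary libraries, and 1778 and 950 of them differed at least 2-fold. Of 668 genes at least 2-fold higher with 10 CPM or more in coronary libraries, 154 (23.05%) were also at least 2-fold higher in coronary replicate 3 than in replicate 1, against 2.64% of all tested genes at that level. Another 372 of the 668 were higher in replicate 1 than in replicate 3, as were 5621 of all 9377 tested genes at that level. In the camera test with a preset correlation, the capillary (adjusted p = 5.48e-11), arterial (2.44e-15), tip cell (1.27e-10), cell cycle (1.02e-09), glycolysis (1.84e-09), fibroblast (5.38e-07), Wnt target (6.39e-05), mural (0.000838), valve (0.00087) and epicardial (0.0407) lists moved up. The interferon (6.12e-06), endocardial (0.0108) and imprinted (0.0125) lists moved down. None of these calls held with an estimated correlation, where in the same order the adjusted p with an estimated correlation was 0.267, 0.0835, 0.267, 0.342, 0.272, 0.272, 0.272, 0.272, 0.448 and 0.272 for lists moving up, and 0.193, 0.273 and 0.322 for those moving down. The epicardial call was lost with DESeq2 size factors (camera adjusted p = 0.0504) and without 1 library, at 0.0551, 0.0667 and 0.0672 without E13 coronary replicates 1, 3 and 4 and 0.0551 and 0.0543 without E17 endocardial replicates 1 and 2. The venous list did not pass (camera adjusted p = 0.238). Adjusted over the list alone, 12 valve genes, 9 epicardial genes and 2 interferon genes were higher, 2 Wnt target genes were lower, and the other counts given here were the same.

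Signalling lists were mixed at E13. Of the 17 Notch genes, 10 were higher in coronary libraries, among them the ligand gene Jag2 (3.85 ± 0.16), and 6 were lower. Of the 18 guidance genes, 10 were higher and Sema3a, Plxnd1, Ephb4 and Epha4 were lower. Both lists moved up (camera adjusted p = 0.0108 and 0.000925, adjusted p = 0.272 and 0.149 with an estimated correlation). The glial and neural crest genes Fabp7, Tubb3, Erbb3 (5.78 ± 0.42) and S100b were higher, and the other of the 5 tested was lower. This list passed only with the batch block (adjusted p from 0.0624 to 0.0122, and adjusted p = 0.179 with an estimated correlation) or without 1 library, at 0.00217 without E13 coronary replicate 1. Tubb3 and Erbb3 were lowest in coronary replicate 1 and highest in replicate 3, as the fibroblast genes were. With the block the edgeR adjusted p of Fabp7 was 0.0778, and its call was also lost without 1 library, at 0.119 and 0.105 without E13 endocardial replicates 1 and 2, 0.0688, 0.0983 and 0.0733 without E13 coronary replicates 1, 2 and 3 and 0.0526 and 0.053 without E17 endocardial replicates 1 and 2. The fatty acid list, with 8 genes higher and 7 lower of 21, also passed only with that block (adjusted p from 0.586 to 0.0185, and adjusted p = 0.436 with an estimated correlation). The counts of these 4 lists were the same when adjusted over the list alone.

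**Figure D2:**
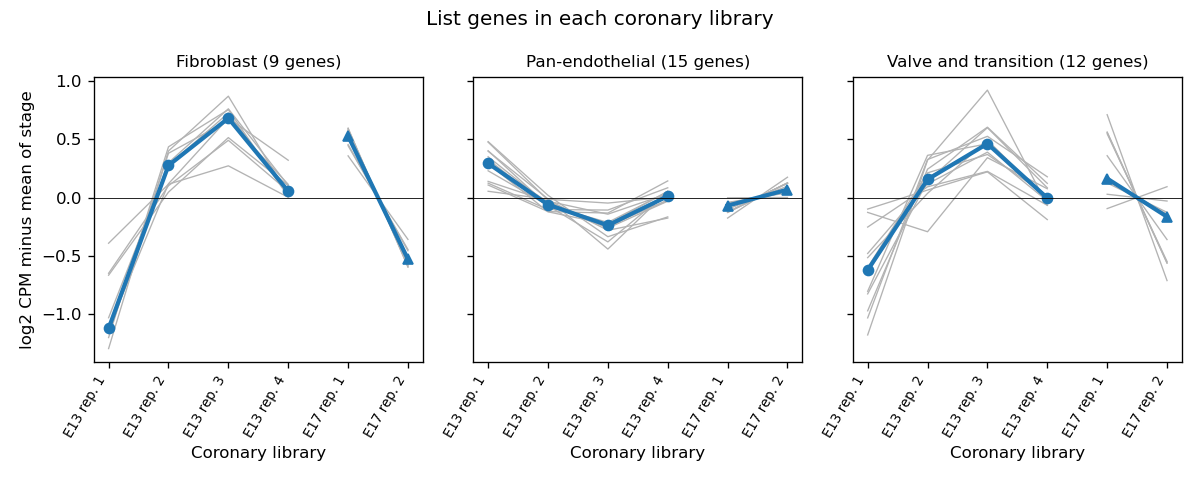
Genes of 3 lists with a mean of at least 10 CPM in E13 coronary libraries, as log2 CPM minus the mean over the coronary libraries of the stage, with 1 thin line per gene, the list median as a thick line, and replicates in no order. In the 4 E13 coronary libraries all 9 fibroblast genes are lowest in replicate 1 and highest in replicate 3, and all 15 pan-endothelial genes are lowest in replicate 3.

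At E17 the same populations differed more widely in endocardial genes. Of the 15 endocardial genes, 13 were lower in coronary libraries, with Npr3 at -7.65 ± 0.26 (2314 ± 129.7 against 11.5 ± 0.0279 CPM), Cdh11 at -5.44 ± 0.17 and the transcription factor gene Hand2 at -4.41 ± 0.12. Tbx20 was higher and Hapln1 did not pass at -0.26 ± 0.20. All 15 capillary genes were higher in coronary libraries, among them the carbonic anhydrase gene Car4 (8.31 ± 0.47), Meox2 (6.08 ± 0.33) and Btnl9 (6.03 ± 0.32). Plvap, which encodes the diaphragm protein of fenestrae, was lower by a large margin (-6.40 ± 0.19, 1532 ± 107 against 18.1 ± 2.59 CPM), and the tight junction gene Cldn5 was higher (5.54 ± 0.30).

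Arterial genes were again higher in E17 coronary libraries, 15 of 18, with the semaphorin gene Sema3g at 5.83 ± 0.26 and the Notch ligand gene Jag2 at 5.30 ± 0.23. Bmx was lower (-3.73 ± 0.14), and Gja4 and Nrp1 did not pass at -0.16 ± 0.12 and 0.11 ± 0.10. 7 of 12 venous genes were lower, including Nr2f2 (-1.87 ± 0.07) and Vwf (-3.37 ± 0.15), while Aplnr (4.69 ± 0.27), Nrp2 and Flt4 were higher and Ephb4 and Il1r1 did not pass at -0.19 ± 0.13 and -0.04 ± 0.21. With the batch block, Ephb4 passed as lower (edgeR adjusted p = 0.0415). All 32 cell cycle genes were higher in coronary libraries, such as Mki67 (1.88 ± 0.13) and Cenpa (1.69 ± 0.12). 13 of 14 tip cell genes were higher, with Apln at 4.84 ± 0.35, and Angpt2 was lower. 12 of 16 glycolysis genes were higher, with Pfkp at 2.22 ± 0.18, and Hk2, Pfkfb3, Aldoc and Pgam1 did not pass at -0.20 ± 0.25, 0.33 ± 0.14, -0.63 ± 0.42 and 0.14 ± 0.12, of which Pfkfb3 passed with the batch block (edgeR adjusted p = 0.0167).

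9 of 15 imprinted growth genes were lower in E17 coronary libraries, with H19, an abundant noncoding RNA, at -2.40 ± 0.09 and the growth factor gene Igf2 at -1.90 ± 0.09, and Mest, Grb10 and Peg10 were higher. Basement membrane genes were mostly higher, 10 of 14, among them Nid2 (3.91 ± 0.21) and Sparc (1.22 ± 0.10), while Agrn was lower and Col18a1, Lama5 and Nid1 did not pass at 0.16 ± 0.07, -0.26 ± 0.11 and -0.16 ± 0.07. The largest coronary excesses were in the homeobox gene Tlx1 (8.47 ± 0.80), Car4, the inducible nitric oxide synthase gene Nos2 (7.63 ± 0.36), Ssu2 (7.52 ± 0.53), the glycerol channel gene Aqp7 (7.47 ± 0.57) and Tnfrsf9 (6.93 ± 0.69). Tlx1 had 1 count in E17 endocardial and 407 in E17 coronary libraries, a CPM ratio of 442 (95% exact interval 78.9 to 17500.0), Car4 3 counts in E17 endocardial and 962 in E17 coronary libraries, a CPM ratio of 348 (95% exact interval 119 to 1692) and Tnfrsf9 3 counts in E17 endocardial and 369 in E17 coronary libraries, a CPM ratio of 134 (95% exact interval 45.4 to 651). The largest deficits were in Mal (-8.89 ± 0.34), the neurexin gene Nrxn3 (-8.19 ± 0.42), the choline transporter gene Slc5a7 (-8.13 ± 0.43), the apolipoprotein gene Apoc1 (-8.10 ± 0.71), Dsg2 (-7.70 ± 0.38) and Npr3. Nrxn3 had 3 counts in E17 coronary and 1013 in E17 endocardial libraries, a CPM ratio of 311 (95% exact interval 106 to 1510.0) and Apoc1 1 count in E17 coronary and 350 in E17 endocardial libraries, a CPM ratio of 322 (95% exact interval 57.5 to 12760.0), and these exact intervals cover counting error only. Of the other-cell markers, 10 of 12 mural genes were higher in E17 coronary libraries, with Kcnj8 at 5.12 ± 0.26 and Rgs5 at 5.73 ± 0.62, and Pdgfrb and Cnn1 did not pass at -0.09 ± 0.39 and 0.87 ± 1.05. 7 of 11 fibroblast genes were higher, such as Ogn (5.69 ± 0.53) and Col1a1 (4.54 ± 0.64), Lum and Dcn were lower, and Col1a2 and Pdgfra did not pass at 0.42 ± 0.43 and -0.85 ± 0.50. The 2 E17 coronary libraries also differed in these markers. Of the members with at least 10 CPM in E13 coronary libraries, 9 of 9 fibroblast genes (median log2 ratio 1.06), 9 of 9 mural genes (0.90) and 11 of 12 valve genes were higher in E17 replicate 1 than in replicate 2, and 0 of 15 pan-endothelial genes were.

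At E17, 7977 genes passed the edgeR test, 4022 higher and 3955 lower in coronary libraries, and 1587 and 1737 of them differed at least 2-fold. The endocardial list moved down in camera (adjusted p = 5.6e-29) and held with an estimated correlation (adjusted p = 0.00397). Up-moving lists were capillary (camera adjusted p = 5.92e-17), arterial (9.19e-11), cell cycle (1.13e-16), tip cell (3.01e-09), mural (0.000567), basement membrane (0.00551) and glycolysis (0.00617), and the imprinted list moved down (0.00036). These were lost with an estimated correlation, where in that order adjusted p was 0.146, 0.105, 0.277, 0.277, 0.277, 0.609, 0.615 and 0.277 with an estimated correlation. With the batch block and an estimated correlation the capillary list did pass (adjusted p = 0.0382). The venous list moved down (camera adjusted p = 0.0385, adjusted p = 0.277 with an estimated correlation) and lost its call with the batch block (adjusted p = 0.218) and without 1 library, at 0.107 and 0.106 without E13 coronary replicates 1 and 3 and 0.0677 and 0.0724 without E17 coronary replicates 1 and 2, and the fibroblast list gained one with it (from 0.0806 to 0.036, and adjusted p = 0.57 with an estimated correlation) and without E17 coronary replicate 2 (camera adjusted p = 0.00286). When adjusted over the list alone, 13 glycolysis, 11 basement membrane and 5 imprinted genes were higher and 3 basement membrane genes lower. All other counts given here were the same. Each group holds 2 libraries, and the gate of the coronary ones is not given.

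Other lists also moved at E17. The pan-endothelial genes were mostly higher in coronary libraries, 11 of 15, with Cldn5 named above, and Tek, Tie1 and Eng were lower. Of 21 BMP and TGF-beta genes, 11 were lower, and Bmp2, Bmp4, Acvrl1, Id1 and Id3 were higher. Of 21 fatty acid genes, 9 were higher, such as Gpihbp1 (5.10 ± 0.38) and Mgll (4.08 ± 0.28), and Fabp5, Slc27a1, Slc27a3 and Acadm were lower. In the Notch list 10 of 17 were higher and Notch1, Notch2, Dll1, Hes1 and Maml2 were lower, and in the guidance list 11 of 18 were higher and Sema3a, Slit2, Slit3, Ntn1 and Epha4 were lower. The camera adjusted p was 0.00708 for pan-endothelial, 0.02 for BMP and TGF-beta, which moved down, 0.02 for fatty acid, 0.014 for Notch and 0.0172 for guidance. In that order the adjusted p was 0.615, 0.47, 0.47, 0.277 and 0.146 with an estimated correlation. The guidance call was lost with the batch block (adjusted p = 0.0697) and without 1 library, at 0.0781 without E17 endocardial replicate 2, and the Notch call at 0.0892 without E17 endocardial replicate 2. At E17, adjusted over the list alone, 12 pan-endothelial and 12 fatty acid genes were higher, and the other counts of these lists were the same.

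Much of the population difference was shared by the stages. Of the genes called at both, 2610 were higher in coronary libraries at both stages and 2599 lower at both, against 1211.0 and 1183.0 for independent lists, and 663 changed direction. Per direction a Fisher exact test, taken on both sides, across genes gave a p too small for double precision, and genes are not independent replicates. Across the 15171 genes the fold changes of the stages had a Pearson r of 0.569.

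In endocardial cells the stage comparison showed fewer cell cycle and fetal timing transcripts at E17 and more flow response, immediate early and interferon transcripts. 8 of the 9 tested fetal timing genes fell, led by the chromatin gene Hmga2 (-2.84 ± 0.08, 77.1 ± 5.1 to 10.7 ± 0.415 CPM), Arid3a (-2.10 ± 0.11) and the RNA-binding protein gene Igf2bp1 (-1.55 ± 0.09), and Trim71 did not pass, with 2 counts in E17 endocardial and 12 in E13 endocardial libraries, a CPM ratio of 2.49 (95% exact interval 0.555 to 22.9). Of 32 cell cycle genes, 28 fell, with the replication licensing genes Mcm4 at -0.72 ± 0.07 and Mcm2 at -0.57 ± 0.06, and Ccna2, Pcna, Cdc20 and Prc1 did not pass at -0.41 ± 0.17, -0.09 ± 0.09, -0.33 ± 0.13 and -0.28 ± 0.17. 9 of 12 flow response genes rose, among them the endothelin gene Edn1 (1.60 ± 0.11), Klf6 (1.15 ± 0.08) and Cyp1b1 (5.85 ± 0.48), and Nos3, Ankrd1 and Piezo1 did not pass at -0.20 ± 0.10, -0.13 ± 0.21 and 0.17 ± 0.08.

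13 of 16 immediate early and dissociation stress genes also rose in endocardial libraries, with Atf3 at 2.43 ± 0.21 and Zfp36 at 2.30 ± 0.25, and Hspa1a, Hspa1b and Nr4a1 did not pass at 1.02 ± 0.71, 1.03 ± 0.75 and 0.78 ± 0.31. 11 of 20 MHC class I and interferon genes rose, including Irf1 (2.00 ± 0.16) and Tap2 (1.16 ± 0.14). 10 of 15 capillary genes rose, such as the fatty acid transport genes Cd36 (3.77 ± 0.34, 11.6 ± 3.21 to 160.1 ± 4.47 CPM) and Fabp4 (3.14 ± 0.36), and Car4 fell. 5 of 8 lymphatic endothelial genes rose, namely Lyve1, a gene also known from macrophages (3.19 ± 0.19, 15.8 ± 2.76 to 145 ± 47.6 CPM), Prox1 (0.91 ± 0.12), Reln, Ccl21a and Sema3d, and Mmrn1 fell. The endocardial identity genes went both ways, as Npr3, Cytl1 (2.97 ± 0.16), Nrg1, Bmp6 (2.65 ± 0.16) and Edn1 rose and Nfatc1, Gata5, Adgrg6, Hapln1 (-2.29 ± 0.19) and Irx6 fell. 8 of 21 BMP and TGF-beta genes rose, with Smad7 at 0.81 ± 0.10, and Tgfbr1 and Tgfbr3 fell. The fibroblast genes Col1a2 (1.86 ± 0.36), Pdgfra (1.98 ± 0.42), Lum (4.22 ± 0.41) and Dcn (5.45 ± 0.33) rose and Col3a1 fell. Of 12 leukocyte genes, Csf1r, Lyz2, C1qa, C1qb and C1qc rose and Laptm5 fell. That list did not pass (camera adjusted p = 0.197, adjusted p = 0.678 with an estimated correlation) except without 1 library, at 0.0107 without E17 endocardial replicate 2.

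Processed copies of ribosomal protein genes, 3 in number, gave the largest rises in endocardial libraries, Rpl34-ps1, Rps3a3 (from 0.111 ± 0.184 to 116 ± 36 CPM) and Rps3a2 (9.52 ± 0.57). Rpl34-ps1 had no count in any E13 library and 42.7 ± 45.2 CPM in E17 endocardial libraries. All 3 are uncertain because they share sequence with abundant ribosomal genes. Cyp1b1, Dcn and the protease inhibitor gene A2m (4.85 ± 0.23) followed. The largest falls were in Hbb-y, an embryonic globin gene (-7.65 ± 2.27), Igfbp2 (-3.87 ± 0.38), Camk2a (-2.99 ± 0.24), Slc24a4 (-2.86 ± 0.19), Hmga2 and Apob (-2.75 ± 0.48). The Hbb-y call was lost without either E17 endocardial library, at an edgeR adjusted p of 0.142 and 0.121 without E17 endocardial replicates 1 and 2. That of Pdgfra was lost at 0.0698 without E17 endocardial replicate 1. Haemoglobin genes together held at most 0.0843% of counts in any library.

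The edgeR test called 4830 genes, 2462 higher and 2368 lower at E17, and 723 and 318 of them differed at least 2-fold. Leaving out endocardial replicate 1 of E17 lowered the count to 2928, and leaving out replicate 2 lowered it to 3178. In camera the fetal timing list fell (adjusted p = 1.48e-24) and the flow response list rose (3.21e-10), and both held with an estimated correlation (adjusted p = 0.0033 and 0.0357). The flow response genes rose in the same libraries as the immediate early and dissociation stress genes. Whether these rises share a source, such as handling of the cells, was not tested. Calls lost with an estimated correlation were cell cycle (camera adjusted p = 9.49e-15, adjusted p = 0.343 with an estimated correlation), immediate early (7.55e-12, p = 0.149), interferon (2.59e-06, p = 0.108), capillary (2.5e-05, p = 0.394), lymphatic (0.000755, p = 0.149), BMP and TGF-beta (0.000656, p = 0.258) and fibroblast (0.00797, p = 0.678). The endocardial list did not pass (camera adjusted p = 0.303). In endocardial cells, adjusted over the list alone, 30 cell cycle genes fell, 14 immediate early, 12 interferon, 10 BMP and TGF-beta, 6 lymphatic, 7 leukocyte and 7 endocardial genes rose, and 6 endocardial genes fell. Other counts given here were the same. Each batch held 1 stage, so batch and stage cannot be told apart, and embryo genotype, tamoxifen and gate changed with stage as well.

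Among the other lists in endocardial cells, 10 of 14 tip cell genes rose, led by Angpt2 (3.60 ± 0.17) and Adm (1.84 ± 0.37), and Esm1, Kcne3, Pgf and Trp53i11 did not pass at -0.55 ± 0.35, -0.20 ± 0.33, -0.60 ± 0.26 and -0.22 ± 0.14. The venous genes Nrp2, Vwf (1.54 ± 0.12), Selp, Bst1 and Vcam1 rose and Flt4 and Dab2 fell. Of 18 guidance genes 10 rose and Sema3a, Sema3g, Plxnd1, Robo1 and Slit2 fell, of 14 basement membrane genes 8 rose and Col18a1 fell, and of 21 fatty acid genes 8 rose and Cpt1a, Acadl and Plin2 fell. The camera adjusted p was 0.000755, 0.00799, 0.0248, 0.0319 and 0.0475 in that order, each list moving up, and adjusted p was 0.576, 0.178, 0.149, 0.716 and 0.61 with an estimated correlation. Calls lost without 1 library were guidance (camera adjusted p 0.0648 without E17 endocardial replicate 1), basement membrane (0.0754 without E13 endocardial replicate 2 and 0.102 without E17 endocardial replicate 2) and fatty acid (0.0943 and 0.071 without E13 endocardial replicates 2 and 3 and 0.0594 without E13 coronary replicate 4). There, adjusted over the list alone, 6 venous genes rose and 3 fell, and the other counts of these lists were the same.

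In coronary cells all 15 endocardial genes fell from E13 to E17 and all 15 capillary genes rose. Hand2 fell, at -3.46 ± 0.11 (111 ± 12.4 to 10 ± 0.0065 CPM), as did the transcription factor gene Gata4 at -2.96 ± 0.13, Cdh11 at -3.13 ± 0.14 and Hapln1, a matrix link protein gene, at -4.29 ± 0.21. The metalloproteinase inhibitor gene Timp4 rose by 7.36 ± 0.34 (0.212 ± 0.179 to 37.7 ± 4.09 CPM), and Gpihbp1, which encodes the capillary anchor of lipoprotein lipase, by 3.98 ± 0.27. 14 of 21 fatty acid genes rose, with the lipase gene Lpl at 4.53 ± 0.17 and Mgll at 4.35 ± 0.21, Slc27a1, Slc27a3 and Cpt1a fell, and Slc27a4, Cpt2, Acadl and Plin2 did not pass at -0.08 ± 0.06, 0.09 ± 0.16, -0.14 ± 0.07 and -0.02 ± 0.08. 16 of 20 MHC class I and interferon genes rose, led by Ly6e (4.62 ± 0.12), the peptide transporter gene Tap2 (3.40 ± 0.14) and Ifitm3 (2.01 ± 0.11), and H2-K1, H2-T23, Ifit1 and Ifit3 did not pass at 0.99 ± 0.41, 0.44 ± 0.19, 1.47 ± 0.87 and 0.04 ± 0.65.

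11 of 13 Wnt target genes fell in coronary cells, such as Nkd1 (-2.79 ± 0.17), Apcdd1 (-2.94 ± 0.19) and Axin2 (-3.31 ± 0.37), while Ccnd1 (1.63 ± 0.12) and Sox7 rose. 8 of 15 valve and transition genes fell, with Vcan at -3.26 ± 0.27 and Has2 at -3.52 ± 0.39, and the other 7 did not pass. 14 of 15 pan-endothelial genes rose, including Kdr, the gene of the main VEGF receptor (1.37 ± 0.13), Fli1 (1.15 ± 0.10) and Cldn5 (2.01 ± 0.20), and Tek fell. 11 of 14 basement membrane genes rose, with Sparc at 1.42 ± 0.08, Lama5 fell, and Col18a1 and Agrn lay at 0.01 ± 0.06 and 0.18 ± 0.07. All 9 fetal timing genes fell, with Igf2bp1 at -1.73 ± 0.09 and Hmga2 at -1.30 ± 0.07. 9 of 16 immediate early genes rose, such as Btg2 (1.89 ± 0.21), and the other 7 did not pass. Of 32 cell cycle genes, 8 fell, including Mcm7 (-0.42 ± 0.08), Mki67 rose (0.43 ± 0.11) and 23 did not pass. Among other-cell markers, the fibroblast genes Col3a1, Pdgfra, Lum (-2.10 ± 0.43), Fbln1 (-1.61 ± 0.20) and Mfap4 (-2.81 ± 0.53) fell, Dpt, Tcf21 and Ogn (3.31 ± 0.34) rose, and Col1a1, Col1a2 and Dcn did not pass at 0.04 ± 0.46, 0.04 ± 0.37 and 0.58 ± 0.28. Of 12 mural genes 6 rose, such as Kcnj8 (1.31 ± 0.16) and Rgs5 (2.52 ± 0.38), and Tagln and Cnn1 fell. That list did not pass (camera adjusted p = 0.227, adjusted p = 0.723 with an estimated correlation) except without 1 library, at 0.0424 without E17 coronary replicate 2. Of 10 epicardial genes Upk3b, Upk1b, Krt8, Krt18 and Lrrn4 fell and Wt1, Krt19 and Aldh1a2 rose (camera adjusted p = 0.485, adjusted p = 0.723 with an estimated correlation). The glial and neural crest gene Erbb3 fell, at -6.10 ± 0.62 (18 ± 8.36 to 0.253 ± 0.0663 CPM).

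The largest rises in coronary cells were in the copies Rpl34-ps1 and Rps3a2 (10.67 ± 0.61). Rpl34-ps1 was at least 1290.0-fold higher, against a floor of 3 counts over the E13 group. That bound uses the mean of 12.34 and 83.86 CPM in E17 coronary replicates 1 and 2. Aqp7 (9.38 ± 0.49), Rps3a3 (8.98 ± 0.43), Timp4 and the nucleoside transporter gene Slc28a2 (6.54 ± 0.39) followed. The largest falls were in Hbb-y (-7.97 ± 2.10), the carbonic anhydrase gene Car3 (-6.83 ± 0.95), the cartilage collagen gene Col2a1 (-6.14 ± 0.68), Erbb3, Rimklb (-6.03 ± 0.53) and the embryonic globin gene Hba-x (-5.89 ± 1.83). Calls lost without 1 library were Hbb-y (edgeR adjusted p 0.0573 and 0.0567 without E17 coronary replicates 1 and 2), Hba-x (0.105 and 0.1 without E17 coronary replicates 1 and 2) and Mki67 (0.0552 without E17 coronary replicate 1). The edgeR test called 7604 genes, 3725 higher and 3879 lower at E17, and 1009 and 1654 of them differed at least 2-fold. In camera the endocardial list fell (adjusted p = 1.16e-32), the interferon list rose (7.57e-20) and the fetal timing list fell (6.01e-11), and each held with an estimated correlation (adjusted p = 0.00312, 0.00453 and 0.017). Calls lost with an estimated correlation were capillary (camera adjusted p = 5.49e-18, adjusted p = 0.0785 with an estimated correlation), pan-endothelial (1.93e-07, p = 0.424), basement membrane (6.04e-07, p = 0.421), fatty acid (3.27e-05, p = 0.255), Wnt target (0.00247, p = 0.453), valve (0.00421, p = 0.63) and immediate early (0.0234, p = 0.63). Neither the cell cycle list (camera adjusted p = 0.5) nor the fibroblast list (0.614) passed. Adjusted over the list alone, 18 interferon and 12 basement membrane genes rose and 4 cell cycle and 3 mural genes fell. The other counts given here were the same. The stage comparison carries the same confounding as in endocardial cells. Of the genes with at least 10 CPM, 6 of 8 Wnt target genes were lowest in E13 coronary replicate 1. All 12 valve and all 9 fibroblast genes were highest in replicate 3, where all 15 pan-endothelial genes were lowest. Whether a share of mesenchymal cells that differed between libraries set part of the Wnt target and valve falls or the pan-endothelial rise was not tested.

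Of the tip cell genes, 9 of 14 rose in coronary cells and Kcne3 and Pgf fell (camera adjusted p = 0.000369, adjusted p = 0.48 with an estimated correlation). Of the 13 VEGF and angiopoietin genes, 7 rose, with Kdr named above, and Tek, Angpt1 and Pgf fell (camera adjusted p = 0.0341, adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone, 3 tip cell genes fell and the other counts of these lists were the same.

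**Figure D3:**
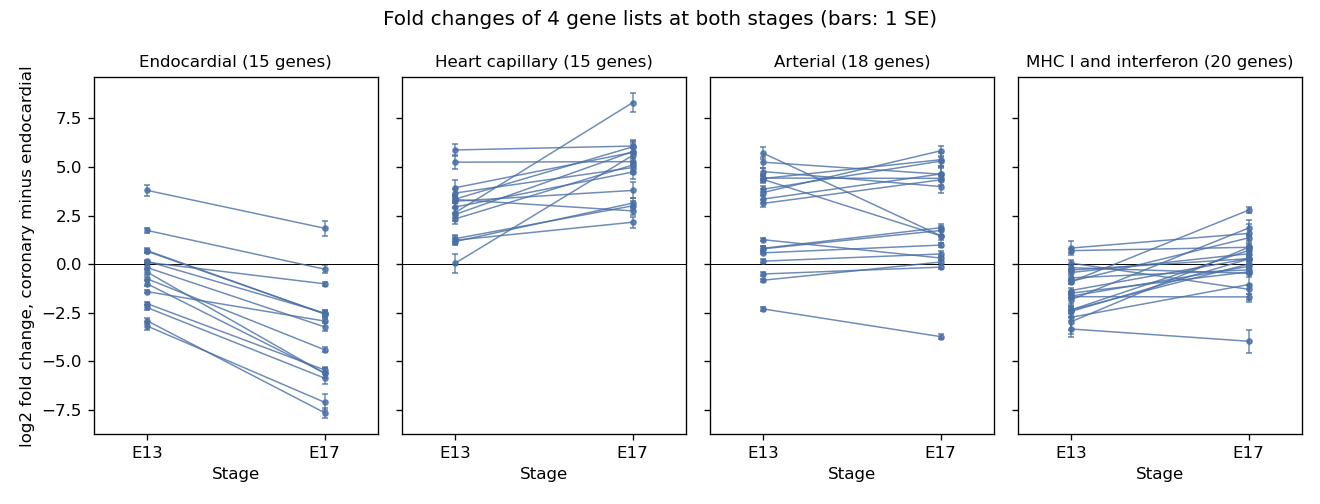
Coronary minus endocardial log2 fold change of each gene on the endocardial, capillary, arterial and interferon lists at E13 (4 against 4 libraries) and E17 (2 against 2 libraries), with 1 line per gene and bars of 1 SE. All 15 endocardial genes had a lower fold change at E17 than at E13, with Npr3 at -2.91 and -7.65, and 13 of the 20 interferon genes a higher one that passed the test of the difference.

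The last comparison tested the change of the population difference between stages, and it can be made within batches. All 15 endocardial genes shifted towards the endocardium at E17, among them Npr3 (-4.74 ± 0.27), Hand2 (-3.66 ± 0.14), Cdh11 (-3.42 ± 0.18) and Edn1 (-3.22 ± 0.17). 13 of 20 interferon genes shifted towards the coronary cells, with Ly6e at 3.69 ± 0.18, Irf7 at 3.07 ± 0.31 and Tap2 at 2.24 ± 0.21, and H2-T23 shifted the other way. 9 of 15 capillary genes shifted towards coronary cells, led by Car4 (5.67 ± 0.60) and Timp4 (5.55 ± 0.67). 17 of 32 cell cycle genes did so, with Mki67 at 1.16 ± 0.16 and Cenpe at 0.98 ± 0.17, as did 12 of 15 pan-endothelial genes, with Kdr at 2.11 ± 0.19, while Tek shifted the other way and Erg and Eng lay at 0.02 ± 0.16 and -0.39 ± 0.14. With the batch block Eng passed as shifted towards the endocardium (edgeR adjusted p = 0.00431).

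9 of 13 Wnt target genes shifted towards the endocardium, among them Nkd1 (-3.64 ± 0.22) and Axin2 (-3.68 ± 0.48), Ccnd1 (1.74 ± 0.18) and Sox7 shifted towards coronary cells, and Tcf7 and Nkd2 did not pass at -0.51 ± 0.46 and -0.06 ± 0.82. 7 of 15 valve and transition genes shifted towards the endocardium, with Vcan at -5.11 ± 0.35 and Twist1 at -4.35 ± 0.66, and Snai2 and Tgfbr3 the other way. The fibroblast genes Col1a2, Pdgfra (-4.03 ± 0.63), Lum (-6.32 ± 0.62), Dcn (-4.87 ± 0.46) and Fbln1 (-1.18 ± 0.27) shifted towards the endocardium and the other 6 did not pass. Prox1 (-3.09 ± 0.20), Lyve1 (-3.26 ± 0.33), Mmrn1 and Nts of the 8 lymphatic genes did so too. 6 of 16 immediate early genes shifted towards the endocardium, such as Ier3 (-1.47 ± 0.27) and Atf3 (-1.48 ± 0.31), and Fos lay at -0.65 ± 0.41. The largest shifts towards coronary cells were in Aqp7 (8.49 ± 1.26), Papln (6.10 ± 0.36), Slc28a2 (5.97 ± 0.63), Car4, Timp4 and Galnt15 (5.01 ± 0.65). Those towards the endocardium were in Lum, the elastin gene Eln (-6.11 ± 0.28), the prostaglandin synthase gene Ptgs2 (-6.10 ± 0.46), Ptx3 (-6.05 ± 1.32), Shisa2 (-5.98 ± 0.66) and Cyp1b1 (-5.73 ± 0.71).

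In the edgeR test of this difference 4962 genes passed, 2465 shifted towards coronary cells and 2497 towards the endocardium. The endocardial list held in camera (adjusted p = 1.1e-45) and with an estimated correlation (adjusted p = 0.000843). The interferon list passed in camera (adjusted p = 1.33e-08), not with an estimated correlation (adjusted p = 0.072 with an estimated correlation), and again once the batch block was added to that (adjusted p = 0.0338). Calls lost with an estimated correlation were capillary (camera adjusted p = 2.21e-05, adjusted p = 0.54 with an estimated correlation), pan-endothelial (2.21e-05, p = 0.549), cell cycle (8.92e-06, p = 0.602), valve (9.84e-05, p = 0.549), lymphatic (0.000396, p = 0.215), Wnt target (0.000441, p = 0.453) and fibroblast (0.0116, p = 0.642). The immediate early list did not pass (camera adjusted p = 0.0621) but did with the batch block (adjusted p = 0.000448, and adjusted p = 0.453 with an estimated correlation). With the p-values adjusted over the list alone, 11 capillary and 23 cell cycle genes shifted towards coronary cells and 12 valve and 2 pan-endothelial genes towards the endocardium, and the other counts given here were the same. The libraries at E17 number 2 per population, and their genotype and gates differ from those at E13. A share of mesenchymal cells that differed between coronary libraries was not separated from the shifts of Wnt target, valve, fibroblast and pan-endothelial genes.

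Further lists shifted between stages. Of 21 BMP and TGF-beta genes, 11 shifted towards the endocardium, such as Bmp6 (-3.26 ± 0.24) and Bmp4 (-3.10 ± 0.31), and Acvrl1, Id1, Tgfbr2 and Tgfbr3 towards coronary cells. Of the 19 on that list with at least 10 CPM in E13 coronary libraries, 12 were highest in replicate 3 and 6 in replicate 1. Of 12 flow response genes, 7 shifted towards the endocardium and Thbd towards coronary cells. Of 15 imprinted genes, 10 shifted towards the endocardium, with H19 at -1.47 ± 0.10, and Dlk1, Mest, Grb10 and Sgce towards coronary cells. The glycolysis genes Hk2, Aldoc, Tpi1, Pgam1 and Eno1 shifted towards the endocardium. Of 14 basement membrane genes, 11 shifted towards coronary cells, such as Col4a2 (1.26 ± 0.18), and Col15a1 and Lama5 towards the endocardium. Of 21 fatty acid genes, 8 shifted towards coronary cells, such as Lpl (3.44 ± 0.25), and Fabp5, Slc27a1 and Slc27a3 towards the endocardium. The camera adjusted p was 0.00042, 0.0012, 0.0197, 0.0418, 0.0018 and 0.00817 in that order, and adjusted p was 0.434, 0.391, 0.549, 0.676, 0.588 and 0.549 with an estimated correlation. Calls changed without 1 library in glycolysis (camera adjusted p 0.0569 and 0.0634 without E13 endocardial replicates 3 and 4, 0.11 and 0.0686 without E13 coronary replicates 1 and 2, 0.183 without E17 endocardial replicate 2 and 0.182 without E17 coronary replicate 1), imprinted (0.0539 without E17 endocardial replicate 2 and 0.057 without E17 coronary replicate 2), fibroblast (0.0618 without E17 coronary replicate 2) and immediate early (0.0231 and 0.0118 without E13 endocardial replicates 1 and 2 and 0.047 without E13 coronary replicate 4). With values adjusted over the list alone, 13 BMP and TGF-beta, 8 flow response and 7 glycolysis genes shifted towards the endocardium, 12 basement membrane and 9 fatty acid genes towards coronary cells. The other counts of these lists were the same.

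Lists of other blood and heart cells and of junctions passed in neither population comparison. Of the 12 junction and barrier genes, 5 were higher and 4 lower in E13 coronary libraries and 8 and 4 at E17 (camera adjusted p = 0.945 and 0.385). The cardiomyocyte list had a camera adjusted p of 0.571 at E13, where Ryr2 was lower, and 0.711 at E17, where Ryr2 and Tnni1 were lower. In the erythroid list Klf1 was higher and Epor lower at E13 (0.833), and none passed at E17 (0.718). In the leukocyte list Csf1r, Mrc1 and Laptm5 were higher and Aif1 lower at E13 (0.571), and Mrc1 and Laptm5 were higher and Cd68 and Csf1r lower at E17 (0.718). In the platelet list 2 of 5 genes were lower and 0 higher at each stage, with Gp1ba lower at both (0.127 and 0.0806). Adjusted over the list alone, 1 cardiomyocyte gene was lower at E17 and the other counts of these lists were the same.

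On GRCm38, Npr3 (ENSMUSG00000022206) lies on chromosome 15 from 11839896 to 11907287 on the minus strand, Plvap (ENSMUSG00000034845) on chromosome 8 from 71497765 to 71511752 on the minus strand, Hand2 (ENSMUSG00000038193) on chromosome 8 from 57320983 to 57324633 on the plus strand, Car4 (ENSMUSG00000000805) on chromosome 11 from 84957786 to 84966044 on the plus strand, Unc5b (ENSMUSG00000020099) on chromosome 10 from 60762593 to 60831581 on the minus strand, Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042 on the plus strand and Hmga2 (ENSMUSG00000056758) on chromosome 10 from 120361275 to 120476469 on the minus strand. These are whole gene spans, and the counts of each gene pool all of its annotated exons.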

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

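All tests of explanations here were chosen after the result was seen, except the splits of the E13 libraries, which were planned.

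In groups of 4 libraries, the gap of the highest or lowest library to its neighbour was taken over the whole range. It was compared with Dixon's 95% critical value for 4 samples. This was done for each gene with a value in the text and for library measures such as the total and the mitochondrial share. Of 376 such tests, 21 exceeded the critical value, all of them for genes, and chance alone marks about 1 in 20 groups. The gap shares by library were as follows. In E13 endocardial replicate 1 Klf6 (0.932), Ptgs2 (0.967), Wnt7a (1) and Xist (0.954). In E13 endocardial replicate 2 Pfkfb3 (0.84), Rps3a3 (0.845), Smad7 (0.926) and Tlx1 (1). In E13 coronary replicate 1 A2m (0.951), Axin2 (0.873), Hmga2 (0.86), Irf7 (0.861), Nos2 (0.916), Nrp1 (0.904), Sp5 (0.851) and Sparc (0.858). In E13 coronary replicate 3 Apoc1 (0.843) and Pfkfb3 (0.867). In E13 coronary replicate 2 H2-K1 (0.966), Rps3a2 (1) and Timp4 (0.836). The flags of Wnt7a, Tlx1 and Rps3a2 lie at the floor. They set 0.07517, 0.04803 and 0.2165 CPM against 0 in every other library of the group. Those of Rps3a3, Sp5 and Timp4 lie near it. They set 0.3843 CPM against at most 0.05947, 0.05409 against at least 0.4801 and 0.4764 against at most 0.1623 CPM.

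The coronary minus endocardial effect differed between E17 and E13 in 4962 genes by edgeR's test of the difference. Camera adjusted p with the preset and then an estimated correlation follows, and only endocardial identity passed with both. Lists whose effect rose towards coronary cells had a camera adjusted p as follows: heart capillary identity (2.21e-05, 0.54), cell cycle (8.92e-06, 0.602), fatty acid uptake and oxidation (0.00817, 0.549), basement membrane (0.0018, 0.588), pan-endothelial (2.21e-05, 0.549) and MHC class I and interferon (1.33e-08, 0.072). Lists that moved towards the endocardium were endocardial identity (1.1e-45, 0.000843), BMP and TGF-beta pathway (0.00042, 0.434), Wnt pathway targets (0.000441, 0.453), glycolysis (0.0418, 0.676), valve and endothelial-to-mesenchymal transition (9.84e-05, 0.549), flow response (0.0012, 0.391), imprinted growth genes (0.0197, 0.549), fibroblast markers (0.0116, 0.642) and lymphatic endothelial markers (0.000396, 0.215) by the same camera adjusted p. Named genes with a positive difference on the log2 scale were Aqp7 (8.49), Papln (6.10), Slc28a2 (5.97), Car4 (5.67), Timp4 (5.55), Galnt15 (5.01), Ly6e (3.69), Lpl (3.44), Irf7 (3.07), Tap2 (2.24), Kdr (2.11), Ccnd1 (1.74), Col4a2 (1.26), Mki67 (1.16) and Cenpe (0.98). Those with a negative one were Lum (-6.32), Eln (-6.11), Ptgs2 (-6.10), Ptx3 (-6.05), Shisa2 (-5.98), Cyp1b1 (-5.73), Vcan (-5.11), Dcn (-4.87), Npr3 (-4.74), Twist1 (-4.35), Pdgfra (-4.03), Axin2 (-3.68), Hand2 (-3.66), Nkd1 (-3.64), Cdh11 (-3.42), Bmp6 (-3.26), Lyve1 (-3.26), Edn1 (-3.22), Bmp4 (-3.10), Prox1 (-3.09), Atf3 (-1.48), H19 (-1.47), Ier3 (-1.47) and Fbln1 (-1.18).

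Of the 35 splits of the 8 E13 libraries into 4 and 4, 1, the real split, gave 9106 genes or more. The highest of the others, those that part every batch pair included, gave 1 gene. Each of the others mixes the populations within its groups, so their difference counts as spread and few calls can arise. The splits therefore cannot tell what part of the E13 calls arose by chance.

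Genes of mesenchymal cells were higher in E13 coronary libraries, and fibroblast, valve and 7 of 9 mural genes measured at 10 CPM or more were lower in replicate 1 than in replicate 3. Free RNA of the whole ventricle is argued against as the source of the excess over endocardial libraries. No cardiomyocyte gene passed as higher, and their median log2 fold change was -0.23. Between coronary libraries, 6 of 9 cardiomyocyte genes at 10 CPM or more were highest in E13 replicate 3 and 2 in replicate 1. All 9 were higher in E17 replicate 1 than in replicate 2. The median log2 ratio of E13 replicate 3 over replicate 1 was 0.123 for cardiomyocyte, 1.68 for 6 erythroid and 1.805 for the fibroblast genes. Whether free RNA added to the spread between replicates was not tested. Mesenchymal cells at a share that varies between the sorted samples may be the source: 9 of the 9 fibroblast genes measured at 10 CPM or more were highest in coronary replicate 3, where all 15 pan-endothelial genes were lowest. The CD31 gate would remove such cells if it were complete. Endothelial cells in transition to mesenchyme stay open, because valve genes were higher with the fibroblast genes, with a median log2 ratio of 1.06 of replicate 3 over replicate 1, and these cannot be told apart in bulk RNA.

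Endocardial genes, with the exceptions Hapln1 and Tbx20, lay nearer the endocardial level in E13 than in E17 coronary libraries. Carry-over of endocardial cells as the whole source is argued against, since Dsg2 stood at 7.39% of its endocardial level in E13 coronary libraries and the median endocardial list gene at 75.97%, with 12 of 15 above 3 times the former. For Npr3, Irx6 and Adgrg6, the lowest at 11.03%, carry-over cannot be told apart from expression. Of the 14 list genes with at least 10 CPM in E13 coronary libraries, 8 were lowest in replicate 1 and 8 highest in replicate 3. The other way, 1 was highest in replicate 1 and 2 were lowest in replicate 3. Their median log2 ratio of replicate 3 over replicate 1 was 0.37. Whether the mesenchymal cells considered above added to the levels of these genes was not tested. A gate low in endomucin at E17 only also stays open, as the Emcn difference between stages was -0.45 and did not pass the edgeR test (adjusted p = 0.057, 0.0243 with the batch block, and 0.00957 to 0.298 over all alternatives). A biological change of coronary cells between stages, which the design names, may also account for it and was not separable from genotype or gate.

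Processed copies of the ribosomal genes Rpl34 and Rps3a1 were counted at E17 and hardly at E13. Reads shared with the parent gene may be the source. From batch 5 to batch 6 each parent fell. The sum of parent and copies moved by at most 0.10 on the log2 scale in both populations. That compares the 2 E17 batches, not the stages. Between stages, the Rps3a1 sum in coronary libraries was 863.1 to 980.5 CPM at E13, and 1087 and 1123 CPM at E17. In endocardial libraries it was 898.5 to 928.1 CPM at E13, and 972.5 and 906.2 CPM at E17. A strain or genotype variant against the reference could also direct reads to the copies. The share of Rpl34 reads given to its copy reached 24.5% in batch 6 and 3.46% and 3.81% in batch 5, and batch, genotype and stage cannot be told apart here. No biological explanation was tested.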

How the results depend on the processing

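All alternatives named here were planned before the data were examined. No call reversed direction. Of the counts of calls, 122 of the alternative values stayed within 1.5 times the reported value and 3 did not: endocardial E17 minus E13 gave 2928 and 3178 genes without an E17 endocardial library, against 4830 with both, where fewer libraries set the spread, and the list calls fell from 71 to 7 with an estimated correlation. With 1 library left out the counts ran from 8417 to 9190 for E13, 6502 to 8180 for E17, 2928 to 5211 and 5557 to 7715 for the endocardial and coronary stage comparisons, 3568 to 5343 for the difference between stages, and 67 to 72 for lists. A group left with 1 library is assumed to vary like the others. The replicate block by batch gave 9112, 7957 and 4963 genes and moved list calls from 45 to 47 in those comparisons, and it changed no call of a named gene or list beyond those given with the results. Same-direction overlap was 5209 genes, 5238 with the block, 5213 with DESeq2 size factors and 3898 at a threshold of 0.01. Of 270 named gene results 231 kept their call in every alternative, and of 155 list results 79 did. With limma-voom and with batch as a random effect, Fabp7 at E13 (limma adjusted p = 0.0858 and 0.0721), Car3 in the coronary stage comparison (limma adjusted p = 0.138 and 0.141), Hba-x there (0.435 and 0.411), Ptx3 in the difference between stages (0.082 and 0.074) and Hbb-y in both stage comparisons did not pass, and the cause was not tested. Fabp7 also did not pass in the DESeq2 Wald test (adjusted p = 0.0541) or in edgeR with no filter (adjusted p = 0.0528). Over all alternatives the adjusted p of Car3 ran over 2.4e-11 to 0.141 and that of Ptx3 over 4.74e-07 to 0.082. Genes reported as not passing that passed when 1 library was left out had these edgeR adjusted p: at E13 Ccnd1 (0.0171 and 0.0172 without E17 endocardial replicates 1 and 2 and 0.0481 without E17 coronary replicate 2), Efnb2 (0.0365 without E13 coronary replicate 3), Gata4 (0.00705 without E13 coronary replicate 1), H2-K1 (0.0102 without E13 endocardial replicate 2 and 0.044 without E13 coronary replicate 1), Pdgfrb (0.0353 without E13 coronary replicate 3), Postn (0.00322 without E13 coronary replicate 1 and 0.0276 and 0.0317 without E17 coronary replicates 1 and 2), Tgfb2 (0.00328 without E13 coronary replicate 1) and Upk3b (0.00261 without E13 coronary replicate 2); at E17 Col18a1 (0.039 without E13 coronary replicate 1 and 0.0243 without E17 coronary replicate 1), Hapln1 (0.0118 without E17 endocardial replicate 2), Lama5 (0.0447 without E13 coronary replicate 3 and 0.0364 without E17 endocardial replicate 2), Pdgfra (0.0478 without E13 coronary replicate 1) and Pfkfb3 (0.0496 and 0.0258 without E13 coronary replicates 1 and 3 and 0.0149 without E17 endocardial replicate 2); between stages in endocardial cells Ccna2 (0.0472 without E13 endocardial replicate 3 and 0.0112 without E17 endocardial replicate 2), Cdc20 (0.0298 without E13 endocardial replicate 3), Nos3 (0.0462 without E13 coronary replicate 3), Nr4a1 (0.00707 without E13 endocardial replicate 2), Pgf (0.0239 without E17 endocardial replicate 1) and Piezo1 (0.0431 without E13 coronary replicate 3) and in coronary cells Agrn (0.0447 without E13 endocardial replicate 2 and 0.0467 without E17 coronary replicate 1), Dcn (0.0339 without E13 coronary replicate 3 and 0.0147 without E17 coronary replicate 2), H2-K1 (0.0368 and 0.0358 without E13 endocardial replicates 1 and 2 and 0.0111 without E13 coronary replicate 2) and H2-T23 (0.0456 without E13 endocardial replicate 2 and 0.0383 without E13 coronary replicate 2); and for the difference between stages Emcn (0.00957 without E13 coronary replicate 2 and 0.0248 without E17 endocardial replicate 1) and Eng (0.04 and 0.0349 without E13 coronary replicates 2 and 3 and 0.0121 without E17 coronary replicate 2). Depth limits genes near the filter: thinning all libraries to the smallest total left 14922 genes tested and 8825 called at E13.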

Other observations

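The genes in this part were chosen after their values were seen, and no test of an explanation is given.

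A few genes known from liver and plasma, picked by eye, differed between the populations. Lbp, which encodes a lipopolysaccharide carrier, had 168 ± 38.6 against 6.6 ± 1.53 CPM at E17. Ahsg, the fetuin gene, and Cp, the ceruloplasmin gene, rose in endocardial cells between the stages by 4.13 ± 0.32 and 3.69 ± 0.28, to 64 ± 1.87 and 41.3 ± 15.3 CPM, while their E17 coronary levels were 1.07 ± 0.441 and 2.47 ± 0.869 CPM. Apob, another such gene, went the other way between the stages (-2.75 ± 0.48).

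The cartilage genes Col9a1 and Col9a3 stood at 68.9 ± 39 and 52.8 ± 23.4 CPM in E13 coronary libraries, against 3.33 ± 0.865 and 0.55 ± 0.27 CPM in the endocardial libraries, and Sox9, a regulator of cartilage and valve genes, at 43.1 ± 23 against 0.573 ± 0.16 CPM (6.18 ± 0.51, edgeR adjusted p = 7.33e-07). Comp, another cartilage gene, was low there, at 4.64 ± 2.02 against 54.5 ± 5.77 CPM. Col9a1, Col9a3 and Sox9 were lowest in coronary replicate 1 and highest in replicate 3, as the fibroblast genes were. In E17 coronary libraries Col9a1 and Col9a3 were at 1.44 ± 1.27 and 1.54 ± 1.5 CPM. At E17 the coronary libraries instead held the efflux pump gene Abcb1a at 124 ± 17.8 CPM, against 7.31 ± 2.52 CPM at E13 (4.09 ± 0.23, edgeR adjusted p = 7.4e-08). The interferon-inducible genes Ifi203 and Mndal lay at 71.3 ± 20 and 29.1 ± 4.86 CPM in E17 coronary libraries and below 6 CPM in each of the other groups. Xist and the Y-linked gene Ddx3y were counted in all 12 libraries, and both were lower in coronary than in endocardial libraries at E13 (-0.83 ± 0.11 and -0.53 ± 0.10).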
